A study of Homo sapiens with 6 samples.

How the data were processed

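Gene expression was measured in SW480 and SW620 cells, 3 samples per line, with 1 HG-U133A oligonucleotide array (an Affymetrix GeneChip) per sample, per the file headers. Per the labels, the cells were lysed at 60% confluence and total RNA was isolated. The file headers call the arrays of a line samples of a triplicate and do not say whether they came from separate cultures, so p-values measure only the spread between these samples, which may be technical. No 2 arrays held identical values. The deposited values are linear probe set intensities, 1 column per sample. The algorithm that summarised the probes into probe sets, its version and the target of any scaling are not given in the sources used here. The array settings in the deposited experiment files list 1 fluidics station for all arrays, with module 1, 2 or 3 equal to the replicate number in both lines.

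The 2% trimmed means of the deposited intensities differed between arrays by a ratio of up to 1.06, above the tolerance of 5% set for keeping the deposited scaling, so the arrays were quantile-normalised. Median deposited intensities were 22.2 to 24.5. Of 22283 probe sets, 68 AFFX controls and 12 with a total of 14 blank values were left out, which left 22203. Signals under the pooled 20th percentile of 12.3 were raised to it, and log2 values were taken. Differences of genes near this floor are understated. Gene symbols came from the platform annotation, updated through Entrez gene identifiers to the gene table of GRCh38.p14. In all, 19056 probe sets had 1 symbol (19044 found in that table and 12 kept under the platform name), 1043 had several and 2104 had none given here. For each of 11957 genes, the probe set with a single symbol and the highest mean over all 6 arrays was used. The 8256 genes whose mean log2 value lay above the pooled 40th percentile (a signal of 19.1) were tested. Close paralogs can share probes, which was not corrected.

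The lines were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), with Benjamini-Hochberg adjustment over the tested genes and a threshold of 0.05. The comparison, the normalization rule, the filters, 16 gene lists with 529 genes and the rule for naming genes were fixed before the data were examined. Of the listed genes, 469 were measured and 329 tested. Lists were tested with camera at a preset correlation of 0.01, and again with an estimated correlation, each adjusted over the lists. No list was called with the estimated correlation. The lists were: epithelial junctions and keratins, mesenchymal markers and factors of the epithelial-mesenchymal transition, WNT and beta-catenin targets, colon differentiation, proliferation, integrins with laminins and collagens, extracellular proteases and inhibitors, MHC class I antigen presentation, interferon response, EGFR ligands and MAPK feedback, TGF-beta and BMP signalling, death receptors and apoptosis regulators, hypoxia and glycolysis, chemokines with cytokines and receptors, cancer-testis antigens, and stromal, endothelial and leukocyte markers.

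Named were the 10 genes with the largest positive and the 10 with the largest negative difference among called genes whose arrays did not overlap between lines. From each list came up to 4 called members by size of difference, or the 2 brightest members where none was called. CDH1, VIM, MYC, CDX2, EPCAM, CD44, MKI67, ACTB and GAPDH were named whatever their values. A few further list members are given to complete a count and were chosen after their values were seen. Where all 3 arrays of a line lay under the 40th percentile, a fold was computed against that level and written as "at least". Of 46 other probe sets of named genes above the filter, 1 differed in sign. XIST, TSIX and Y-linked genes entered the fit and are not reported.

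The model was tested on simulated data for 8256 genes, with SW620 against SW480 and 200 changed genes. It recovered 24% of the genes raised by 0.5 on the log2 scale, 88% of those raised by 1, 96% of those raised by 2 and 30% of those lowered by 0.5, with 5 false calls among 124. The list test found the 1 list shifted by 0.5 and none of 15 unshifted ones. Genes were drawn independently of one another, so lists whose members vary together were not tested. The 200 changed genes were a far smaller share than the 23.6% of tested genes called in the data. The adjusted threshold was therefore stricter in the simulation, and its recovery rates do not carry over to this comparison. In the simulated list test no gene outside the shifted list was changed, unlike in the data. As alternatives, the deposited scaling, median centring, no floor, a floor at the 40th percentile, an offset, no filter, a filter at the 60th percentile, no intensity trend, the mean of all probe sets, all probe sets tested singly, a replicate block, each array left out in turn and the estimated correlation were run. A spike-in covariate and the omission of a pair of arrays that deviated alike were added after the data were seen.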

Results

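Transcript levels were compared between SW480 and SW620, a pair of human colorectal cancer cell lines derived from the same patient, SW480 from the primary tumour and SW620 from a metastasis. Each line was represented by 3 samples of total RNA from cells collected at 60% confluence, and each sample was hybridised to 1 oligonucleotide array. The comparison addressed which transcripts differed between a primary tumour line and a metastatic line of the same patient. Of 11957 genes with a probe set of their own, 8256 passed the intensity filter and were tested. Pairs of arrays of the same line correlated at r = 0.959 to 0.979 over the tested genes, and pairs of arrays from different lines at 0.893 to 0.930. These correlations run across genes, which are not independent replicates. The first principal component, which separated the lines, carried 63.6% of the variance. Precision was limited by the number of arrays, 3 per line. Signals are quantile-normalised intensities given as mean ± SD with n = 3 per line, and differences are log2 values of SW620 minus SW480 with their SE.

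SW620 cells held more mRNA than SW480 cells for VIM, TPM2, CAV1 and TNC, and less for the keratin KRT5, the cyclin CCND2 and the tight junction protein CLDN7. Altogether, 1049 genes were higher and 899 lower in SW620 at an adjusted p under 0.05 (limma with Benjamini-Hochberg adjustment), which was 23.6% of the genes tested. Of these, 225 genes differed by at least 2-fold, 137 of them higher and 88 lower in SW620. In 3165 tested genes, or 38.3%, the 3 arrays of one line all lay above the 3 of the other, where chance gives 10%. The share of called genes that were higher in SW620 was 53.9%, and 68.3% (1261 higher, 586 lower) when each array was centred on its median instead of quantile-normalised. With an offset added in place of the floor, 127 genes differed by at least 2-fold.

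The genes with large rises in SW620 included FXYD6, a regulator of the sodium pump, and TPM2, a tropomyosin of the actin cytoskeleton, for which the floor in SW480 leaves only a lower bound. FXYD6 lay at the floor of 12.3 on all SW480 arrays and at 106 ± 3.42 in SW620, at least 5.56-fold higher (adjusted p = 6.1e-08, limma). TPM2 was at least 5.32-fold higher and TNC, the extracellular matrix glycoprotein tenascin C, at least 4.99-fold higher. VIM, the intermediate filament protein of mesenchymal cells, rose from 75.4 ± 6.91 to 448 ± 28.1 (2.57 ± 0.09, adjusted p = 6.7e-08, limma). CAV1, the coat protein of caveolae, rose from 17.4 ± 3.58 to 120 ± 4.37, and the focal adhesion protein TNS3 from 35.1 ± 3.63 to 246 ± 30.5. CAV1 differed by 2.81, and by 1.46 with its other probe set above the filter. MFNG, a glycosyltransferase that modifies Notch receptors, went from 19.3 ± 0.98 to 122 ± 1.85, and its other probe sets differed by 2.20 and -0.07. The ephrin ligand EFNB2 (2.56 ± 0.16), the lipid phosphate phosphatase PLPP3 (2.62 ± 0.12) and the chromatin reader ZMYND11 (at least 4.32-fold) were the remaining genes of the 10 with the largest log2 differences, a ranking that has no order among genes at the floor. With the mean of all probe sets of a gene in place of the brightest, the differences of TPM2, TNC, MFNG and ZMYND11 were 1.80, 1.46, 1.60 and 1.58, all still called.

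Large falls were those of KRT5, a keratin of basal epithelial cells, and CCND2, a D-type cyclin. KRT5 fell from 706 ± 27.5 in SW480 to 19.7 ± 2.44 in SW620 (-5.17 ± 0.10, adjusted p = 1.1e-09, limma). CCND2 was at 384 ± 8.42 in SW480 and at the floor on all SW620 arrays, at least 20.1-fold lower. Its other probe sets above the filter differed by -3.15 and -2.10. CLDN7 was at least 11.4-fold lower, the iron-carrier protein LCN2 at least 6.90-fold lower, and the insulin-like growth factor binding protein IGFBP3 at least 5.51-fold lower. Another IGFBP3 probe set differed by -2.23. NELL2 and S100A14 were at least 4.72-fold and 4.29-fold lower. KRT23, a further keratin, fell from 308 ± 9.68 to 30.6 ± 4.55. ASS1, the argininosuccinate synthase of arginine synthesis, fell from 459 ± 20.1 to 80.8 ± 6.12, and the stress-response transcription factor ATF5 from 109 ± 1.09 to 19.2 ± 1.18 (-1.49 with the mean of its probe sets).

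**Figure D1:**
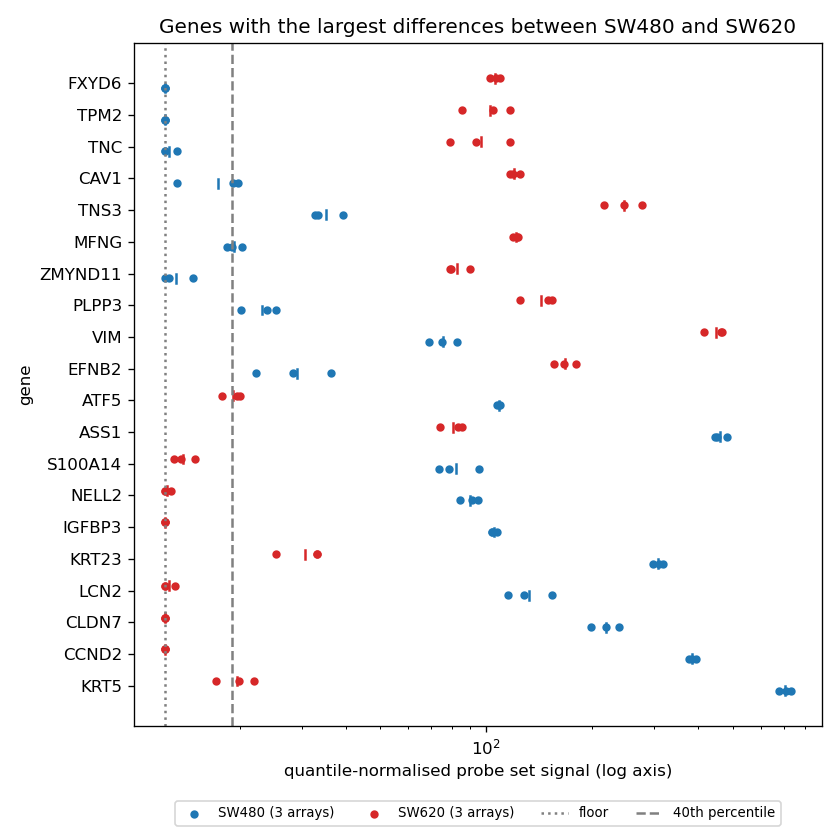
Signals of the 20 genes with the largest differences between the lines, one point per array on a log axis, with SW480 in blue and SW620 in red and a short bar at each mean. The dotted line marks the floor of 12.3 and the dashed line the filter level of 19.1; the SW480 points of FXYD6 and TPM2 and the SW620 points of CCND2, CLDN7 and IGFBP3 all lie at the floor.

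Genes of epithelial junctions and keratins were lower in SW620 as a group. Of 28 tested members 15 fell, 2 rose and 11 did not pass the test, and adjusted over the list alone the counts were 15 and 3. Besides CLDN7, the falls included ST14, a membrane serine protease (-1.45 ± 0.13), the cadherin CDH3 (-1.23 ± 0.11), the protease inhibitor SPINT2 (-1.02 ± 0.08), the adhesion molecule EPCAM (-0.77 ± 0.08) and the epithelial cadherin CDH1 (-0.74 ± 0.15, adjusted p = 0.0056, limma). With the mean of its probe sets ST14 differed by -0.82, and with the offset CDH1 differed by -0.48, both still called. The desmosomal gene DSP and the keratin gene KRT8 rose, by 0.56 and 0.25. The mean difference of the list was -0.53 (adjusted p = 4.0e-05, camera with a preset correlation of 0.01), and the adjusted p = 0.383 with an estimated correlation.

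Among mesenchymal markers and factors of the epithelial-mesenchymal transition, 5 of 17 tested genes rose, none fell and 12 did not pass the test, with the same counts adjusted over the list alone. Beside TPM2 and VIM, the matrix protein gene TGFBI rose from 63.6 ± 6.65 to 137 ± 5.69, CALD1 differed by 0.63 ± 0.20 (adjusted p = 0.048, limma) and S100A4 by 0.21. The list mean of 0.41 did not pass the test (adjusted p = 0.132, camera), and the list median was 0.07. TPM2 (3.05) and VIM (2.57) lay far above that median. With a stricter filter at the 60th percentile of all signals the mean was 0.69 (adjusted p = 0.018, camera). Over all alternatives the mean of this list ranged from 0.19 to 0.69 and its adjusted p up to 0.734 (camera).

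Proliferation genes were higher in SW620 as a group, with 14 of 39 tested members higher, 3 lower and 22 not passing the test, and 17 higher and 3 lower adjusted over the list alone. TK1 and TYMS, enzymes of thymidine nucleotide synthesis, rose by 0.93 ± 0.10 and 0.77 ± 0.06, the mitotic kinase CDK1 by 0.92 ± 0.08 and AURKB by 0.81 ± 0.08. TYMS differed by 0.22 and lost its call with the mean of its probe sets (adjusted p = 0.131, limma). MKI67, the Ki-67 antigen, rose from 64.1 ± 1.93 to 89.1 ± 13.7 (0.46 ± 0.12, adjusted p = 0.015, limma). CCNE1, MAD2L1 and MCM7 fell. The list mean was 0.20 (adjusted p = 0.0037, camera), and the adjusted p = 0.542 with an estimated correlation.

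Targets of WNT and beta-catenin signalling went both ways. Of 16 tested, 6 rose, 4 fell and 6 did not pass the test, and 7 rose and 7 fell adjusted over the list alone. MYC fell from 469 ± 5.05 to 215 ± 19.4 (-1.13 ± 0.08), the cyclin gene CCND1 by 1.54 on the log2 scale (-1.54 ± 0.10) and the WNT antagonist DKK4 by 1.65 on the log2 scale (-1.65 ± 0.13), while the Notch ligand JAG1 rose by 1.39 ± 0.13 (0.87 with the mean of its probe sets). The list mean was -0.09 and its median 0.02, of opposite signs (adjusted p = 0.939, camera). CD44, a cell adhesion receptor on the same list, differed by -0.40 ± 0.17 with its brightest probe set (adjusted p = 0.130, limma), and its other probe sets differed by -0.38, -0.40 and -1.31.

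In the colon differentiation list, 1 of 23 tested genes rose, the secreted trefoil peptide TFF3 (0.72 ± 0.11), and none fell, with the same counts adjusted over the list alone (list mean -0.05, adjusted p = 0.921, camera). CDX2, the intestinal homeobox factor, measured 20.4 ± 5.45 in SW480 and 20.8 ± 3.89 in SW620, close to the filter level of 19.1 (0.04 ± 0.21, adjusted p = 0.905, limma), and the sign of its difference turned with the deposited scaling.

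Genes of the extracellular matrix and its proteases changed in both directions. In the list of integrins, laminins and collagens 4 of 23 rose and 8 fell, and 4 and 11 adjusted over the list alone (mean -0.09, median -0.24, adjusted p = 0.641, camera). TNC and the integrin gene ITGAE (1.08 ± 0.09) rose, and the laminin gene LAMB3 (-1.45 ± 0.13) and the basement membrane collagen gene COL4A2 (-0.99 ± 0.12) fell. Among extracellular proteases and inhibitors 5 of 24 rose and 8 fell, and 5 and 9 adjusted over the list alone (mean -0.12, adjusted p = 0.753, camera). TIMP1, an inhibitor of matrix metalloproteinases, rose from 97.2 ± 9.61 to 295 ± 15.2. The serpin family gene SERPINB5 was at least 1.96-fold and the kallikrein gene KLK10 at least 2.04-fold lower, and the cathepsin gene CTSB fell by 0.79 on the log2 scale. With the floor at the 40th percentile SERPINB5 differed by -0.97, still called.

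Hypoxia and glycolysis genes split evenly, with 7 of 30 higher and 7 lower, and 8 and 8 adjusted over the list alone (mean -0.18, adjusted p = 0.723, camera). The glucose transporter gene SLC2A3 fell from 235 ± 13.5 to 46.0 ± 0.69, the collagen prolyl hydroxylase gene P4HA2 differed by -1.78 ± 0.13, and EPAS1, which encodes the hypoxia-inducible factor HIF-2 alpha, was at least 1.81-fold lower. The glycolytic regulator PFKFB3 rose by 0.85 ± 0.14. EPAS1 differed by -0.76 with the mean of its probe sets and by -0.86 with the floor at the 40th percentile, both called.

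Signalling lists passed no group test. Among EGFR ligands and MAPK feedback genes 5 of 24 rose and 5 fell, and 6 and 5 adjusted over the list alone (mean 0.04, adjusted p = 0.921, camera). SPRY2, a feedback inhibitor of receptor tyrosine kinases, rose by 1.27 ± 0.12, the receptor gene ERBB3 by 0.78 ± 0.14 and the ETS factor gene ETV5 by 0.74 ± 0.09, with 0.39 for ERBB3 and 0.48 for ETV5 with the mean of their probe sets, both still called. The members that fell were CCND1 (-1.54 ± 0.10), the MAPK phosphatase genes DUSP6 (-0.49) and DUSP5 (-0.48), EGR1 (-0.47) and SPRY4 (-0.36). Among genes of TGF-beta and BMP signalling 3 of 19 rose and 5 fell, and 4 and 5 adjusted over the list alone (mean -0.01, adjusted p = 0.939, camera). The receptor gene TGFBR2 rose from 21.4 ± 1.31 to 50.6 ± 3.62 and the inhibitory SMAD6 was at least 1.65-fold higher, while LTBP3 (-0.67 ± 0.13) and BMP7 (-0.66 ± 0.11) fell. The other BMP7 probe sets differed by -0.40, -0.18 and -0.0049, and with the mean of all of them its call was lost (-0.31, adjusted p = 0.0793, limma). TGFBR2 differed by 0.82 with the mean of its probe sets, and SMAD6 by 0.57 with the offset, both still called. Among death receptors and apoptosis regulators 1 of 23 rose and 1 fell, and 0 and 1 adjusted over the list alone (mean -0.02, adjusted p = 0.939, camera). The gene that fell was CYCS, for cytochrome c (-0.79 ± 0.07), and the one that rose was DIABLO (0.31 ± 0.10, adjusted p = 0.045, limma).

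Immune-related lists also passed no group test. For MHC class I antigen presentation 2 of 16 rose and 4 fell, and 2 and 5 adjusted over the list alone (mean -0.14, adjusted p = 0.592, camera). B2M, the light chain of class I molecules, rose by 0.56 ± 0.11, and the immunoproteasome subunit PSMB9 (-0.93 ± 0.21), the chaperone CANX (-0.65 ± 0.07) and HLA-E (-0.48 ± 0.10) fell. The calls of B2M and PSMB9 were lost with no filter (adjusted p = 0.0555 and 0.0760, limma) and that of HLA-E with median centring (-0.34, adjusted p = 0.0712, limma). With the offset PSMB9 differed by -0.60 and stayed called. In the interferon response list 3 of 17 rose and 2 fell, with the same counts adjusted over the list alone (mean 0.04, adjusted p = 0.921, camera). Over the alternatives other than single arrays left out, this mean ran from -0.0166 to 0.348 and was never called. IFITM2 (0.88 ± 0.10), IFITM3 (0.78 ± 0.08) and LGALS3BP (0.53 ± 0.10) rose and ISG20 was lower (-0.56 ± 0.17, and -0.35 with the mean of its probe sets). Among chemokines, cytokines and receptors 2 of 14 rose and 1 fell, likewise when adjusted over the list alone (mean 0.04, adjusted p = 0.939, camera): IL23A (0.84 ± 0.17) and IL4R (0.48 ± 0.12) were higher and IL32 (-0.37 ± 0.10) lower. Of 3 tested cancer-testis antigens none passed the test, also when adjusted over the list alone (mean 0.14, adjusted p = 0.936, camera), with SSX3 at 21.9 ± 4.52 against 25.1 ± 5.75 and PAGE1 at 23.4 ± 1.26 against 21.4 ± 2.87. Of 15 markers of stromal, endothelial and blood cells 1 was lower, HBB (-0.41 ± 0.13, adjusted p = 0.044, limma), and 0 were called adjusted over the list alone (mean -0.07, adjusted p = 0.753, camera).

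**Figure D2:**
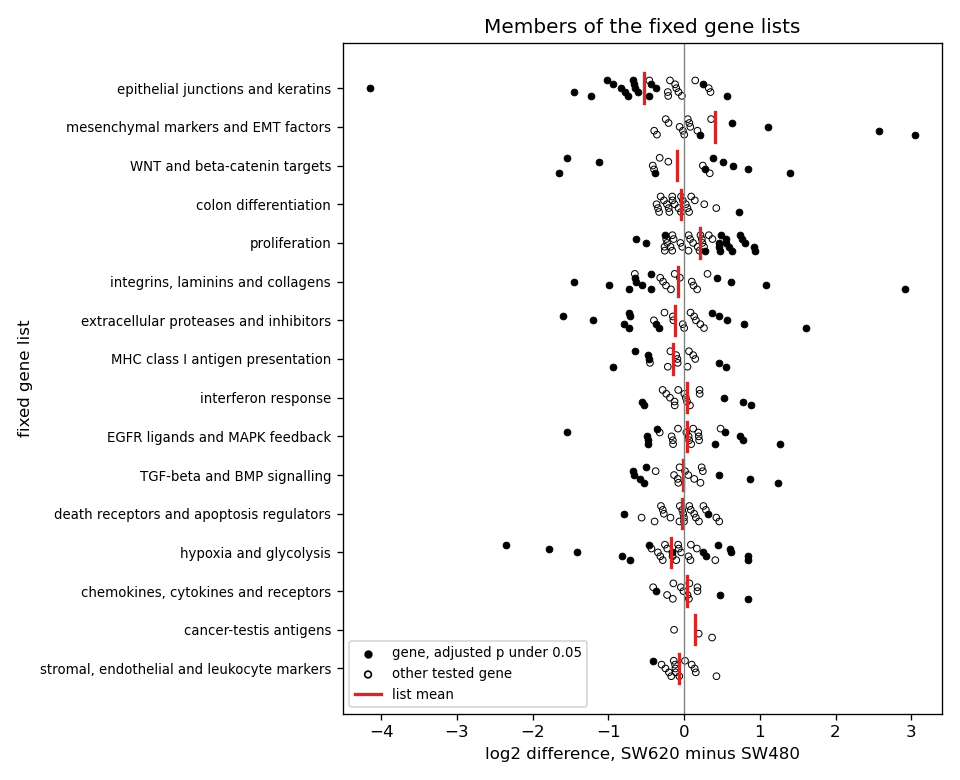
Log2 differences (SW620 minus SW480, horizontal axis) of every tested member of the 16 fixed gene lists, one point per gene, filled where its adjusted p was under 0.05 and open otherwise, with a red bar at the list mean. The mean of the epithelial list lies at -0.53, with CLDN7 at -4.15 farthest to the left, and that of the proliferation list at 0.20.

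Of the genes often used as loading controls, GAPDH differed by -0.08 ± 0.04 (adjusted p = 0.254, limma) and ACTB by 0.14 ± 0.04 (adjusted p = 0.039, limma), and both kept their sign under the deposited scaling (-0.10 and 0.21) and median centring (-0.05 and 0.26). The GAPDH probe set used held the same rank, near the top, on every SW480 array and on SW620 replicate 1, where quantile normalization therefore gave it an identical signal of 2075. Its other probe sets differed by -0.22 and -0.21, and the mean of all of them by -0.17 (adjusted p = 0.0103, limma). The ratio of 3' to 5' control probe set signals, a measure of RNA integrity and labelling, was 1.40 ± 0.0095 for GAPDH in SW480 and 1.60 ± 0.124 in SW620 (exact two-sided permutation p = 0.1, the smallest that 3 against 3 arrays allow). For ACTB it was 1.17 ± 0.036 and 1.18 ± 0.088 (exact permutation p = 1). The calls for CALD1, ISG20, DIABLO, IL4R, IL32, HBB, MKI67 and ACTB were each lost with at least 1 single array left out. The 3 SW480 arrays were washed and scanned in one run and the 3 SW620 arrays in a later one, so run and line cannot be told apart.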

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

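The tests in this part were not among those planned. Probe sets without a single gene symbol entered none of the gene counts of the report, and the same limma model, run over all probe sets, found differences among them. Of 923 tested probe sets with no symbol given here, 73 were higher and 100 lower in SW620, or 18.7%. Of 681 tested probe sets with several symbols, 85 were higher and 84 lower, or 24.8%. Among those with no symbol, one probe set measured 14.4 in SW480, under the filter level of 19.1, and 91.5 in SW620, and another measured 60.0 and 20.4 (-1.55).

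The GAPDH control probe sets, which lie outside the gene comparison, had a 3' to 5' signal ratio of 1.60 in SW620 against 1.40 in SW480, and all SW620 arrays lay above all SW480 arrays.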

How the results depend on the processing

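The spike-in covariate and the omission of 2 arrays that deviated alike were chosen after the data were seen. Under the alternatives fixed in advance with all arrays, 1 value per gene and no block, 870 to 1261 genes were higher and 586 (median centring) to 913 lower in SW620. Genes at least 2-fold different numbered 127 with an offset, which shrinks differences of dim genes by construction, and 178 to 247 otherwise. Testing all 13378 probe sets singly gave 1600 higher, 1411 lower and 378 at least 2-fold different. This counts several probe sets per gene and adds those with no or several symbols. With single arrays left out, 781 to 1024 were higher, 636 to 987 lower and 223 to 246 at least 2-fold different. Without SW480 replicate 2 and SW620 replicate 3, which leaves fewer samples, 722 were higher and 596 lower. With the spike-in covariate the counts were 1127 and 974. The replicate block, which is also the fluidics module, gave 703 higher and 571 lower, and 1272 of its 1274 calls were shared with the unblocked fit. Among named genes, CALD1, ISG20, DIABLO, IL4R, IL32, HBB and ACTB lost their calls with the block. No pairing by replicate number was seen: deviations of same-numbered arrays correlated at -0.41, -0.57 and -0.64, and no array correlated best with its own number. These values also carry the deviation that SW480 replicate 2 and SW620 replicate 3 shared, so a smaller effect of the number is not excluded. The epithelial mean of -0.53 and the proliferation mean of 0.20 kept their calls under all other alternatives run, and lost them with the estimated correlation (adjusted p = 0.383 and 0.542). The mesenchymal list was called only with the filter at the 60th percentile (0.687, adjusted p = 0.018, over a range up to 0.734). Reversals concerned uncalled values, and the cause was not tested. With median centring TGF-beta and BMP signalling turned to 0.0531 and death receptors to 0.0432. With the floor at the 40th percentile cancer-testis antigens turned to -0.00479, and with no filter interferon response to -0.0166. With the filter at the 60th percentile proteases turned to 0.0342 and chemokines to -0.126, and no cancer-testis antigen was left to test. With the mean of all probe sets chemokines turned to -0.0191 and cancer-testis antigens to -0.132. Single arrays left out gave -0.089 to 0.0325 for colon differentiation, -0.0524 to 0.0321 for TGF-beta and BMP signalling, -0.0942 to 0.0068 for death receptors and -0.321 to 0.233 for cancer-testis antigens. CDX2 turned to -0.0019 with the deposited scaling and to -0.0431, -0.0768 and -0.0764 without SW480 replicate 1, SW480 replicate 2 or SW620 replicate 2, and was highest at 0.258 without SW480 replicate 3. Of 1325 values of named genes under alternatives, 1244 kept their direction and side of the threshold, 72 lost a call, 5 gained one and 4 reversed. With the mean of all probe sets, 15 called named genes moved by over 1.5 times and 3 of these, TYMS, BMP7 and HBB (-0.27), lost the call. Lost with single arrays left out were DIABLO (6 of 6 arrays; highest adjusted p = 0.158), ACTB (5; 0.165), IL4R (5; 0.0784), IL32 (5; 0.110), CALD1 (4; 0.155), ISG20 (4; 0.146, and -0.05 without both arrays that deviated alike), HBB (4; 0.172) and MKI67 (1, SW480 replicate 1; 0.0602). CD44 was called without any 1 SW620 array (-1.22, -1.21 and -1.48), where another probe set became its brightest, and with the floor at the 40th percentile (-0.88, adjusted p = 0.00102). Genes near the floor are limited by signal over background.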

Other observations

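Tests chosen only after the result was seen were those of the fluidics module, the spike-in signal, fibroblast genes, loss of 5' ends, the wash run, the neighbours of epithelial genes and shared paralog probes, and the genes named in this part were chosen after their values were seen. Genes that differed between the lines lay in blocks along the chromosomes. Among windows of 25 neighbouring tested genes, 34 that did not overlap passed a genome-wide threshold of 0.05 in each direction in 1000 random gene orders, 16 higher and 18 lower in SW620. The highest, on chromosome 16 from VPS4A to RFWD3, had a mean difference of 0.67 with single genes limited to 1 in size, and 19 of its 25 genes were called higher and 0 lower, among them the quinone reductase NQO1 (1.72 ± 0.10) and the alanyl-tRNA synthetase AARS1 (1.70 ± 0.08). A window on chromosome 19 from PWWP3A to THOP1 held 21 called genes, all higher (mean 0.65), whereas one from CCNE1 to TMEM147 on the same chromosome held 17, all lower (mean -0.49). On chromosome 7 from FIS1 to DLD 16 were lower and 0 higher (mean -0.51). On chromosome 18, 27 of 104 tested genes were lower and 2 higher, and on chromosome 10, 76 of 302 were higher and 14 lower. Some genes named above lay in windows of their own direction, among them EFNB2 and SPRY2 on chromosome 13, ZMYND11 and CDK1 on chromosome 10 and P4HA2 on chromosome 5. CDH3 (-1.23 ± 0.11) and CDH1 (-0.74 ± 0.15) fell although they lie between chromosome 16 windows that were higher, from NOL3 to PRMT7 (mean 0.61) and from VPS4A.

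Genes outside the fixed lists included several known from other tissues. TRBC1, a T-cell receptor constant segment, measured 57.6 ± 9.07 in SW480 and 272 ± 5.51 in SW620, and the lymphocyte kinase LCK 27.1 ± 1.76 and 96.4 ± 4.43. The endoderm factor FOXA2 rose from 20.4 ± 1.67 to 85.4 ± 5.40, and CHGB, a granin of neuroendocrine cells, from the floor to 61.5 ± 7.21. TRIM29, a gene of basal epithelia, fell from 230 ± 9.52 to 77.4 ± 3.56, and KRT13 from 42.5 ± 2.81 to the floor. ASNS, the asparagine synthetase, fell from 294 ± 12.4 to 84.2 ± 16.6, as ASS1 and ATF5 did. ASNS lies in a window of mostly lower genes on chromosome 7, from PON2 to TAF6. ATF5 lies in another lower window, on chromosome 19 from FTL to MYH14 (mean -0.31, 12 genes called lower and 0 higher). Of other genes of amino acid synthesis and shortage, PHGDH fell (-0.77 ± 0.15), while TRIB3, CHAC1, DDIT3, PSAT1 and SHMT2 did not pass the test: TRIB3 differed by -0.26 ± 0.09 (adjusted p = 0.0737, limma), CHAC1 by -0.14 ± 0.16, DDIT3 by 0.18 ± 0.17, PSAT1 by 0.17 ± 0.09 and SHMT2 by 0.21 ± 0.08.

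The mean product of neighbouring genes' standardised differences was 0.229, above the highest value of 0.0331 in 1000 random gene orders (permutation p = 0.001, the smallest they can give), which argues against a chance order. Pairs of arrays within a line gave at most 0.0851, under the 0.229 that a regional trend of equal size between any arrays, such as GC content, would need. That value still exceeded the 0.0331 of random orders of the line difference. Arrays of a line shared a wash run, so these pairs cannot show a regional trend that differed between runs. Without probe sets marked as matching several transcripts and genes with a like-named gene within 12 places, the value was 0.172 over 3956 genes, against at most 0.0502 in 1000 random orders, so probes shared by neighbouring paralogs were not the whole source of the blocks. A candidate explanation is a difference in chromosome copy number between the lines, a hypothesis that was not tested, since no DNA was measured here. The wash run, which coincided with the line, stays open.

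The lower epithelial genes together with higher VIM, TPM2, CAV1 and TNC could come from fibroblasts among the SW620 cells, but COL1A1, COL1A2, COL3A1, DCN, LUM and POSTN differed by a mean of -0.148 (SE 0.0755), with SW620 signals of 12.3 to 77.7. Regional shifts also did not account for the mean of the epithelial list, since the 24 nearest neighbours of each member had a mean difference of 0.0080 (SE 0.046). The bound written first, on the list mean after subtracting the neighbours (-0.53, SE 0.179), was not decisive and was replaced after it was seen. Single members are not settled by this mean: EPCAM, LSR and SPINT2 fell within lower windows, whereas CDH3 and CDH1 fell between higher ones. Loss of 5' ends in SW620 stays open, since the 3' to 5' log2 ratio was higher by 0.183 for GAPDH and by 0.00075 for ACTB. With 0 wash runs holding both lines, run and line cannot be told apart. A difference in epithelial state between the primary and the metastatic line stays among the open explanations, untested.

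SW480 replicate 2 and SW620 replicate 3 deviated from their lines alike (r = 0.715 across genes), along a pattern that held 55.2% of the variance within lines and on which SW480 replicate 3 lay farthest, in the opposite direction (0.557, against -0.465 and -0.552 for that pair). A shared fluidics module cannot be the source, since the highest correlation of same-module arrays was -0.409. Noise of dim probe sets alone is also argued against, because the correlation of this pair was 0.444 in the brightest 25% of genes. In the dimmest 25% it was 0.823, so the pattern was stronger among dim genes, and a part played by low signal stays open. The spike-in signal correlated with the pattern at r = 0.691 over 6 arrays (exact permutation p = 0.194). This met neither bound set for the amount or labelling of the hybridised RNA. The spike-ins used are added already labelled, so they cannot read the labelling of the samples. Both the amount and the labelling stay open. The proliferation list loaded on it at percentile 2.64 of 10000 matched random lists, which was inside the central 95% set as the limit for growth state, but by less than the error of the random draws, so growth state was left open, a choice made after the value was seen. Among the other lists, the lowest were death receptors and apoptosis regulators at percentile 0.45 and mesenchymal markers at 3 of 2000 random lists. The highest was that of stromal, endothelial and leukocyte markers at 94.9. These extremes were picked without adjustment over the lists. Random lists also took no account of members that vary together, which can make a list look extreme.

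Of the 10 splits of the 6 arrays into 3 and 3, only 1, the real one, gave as many as 1948 genes, and the highest other gave 8. With 10 splits the share cannot fall under 0.1. All other splits put arrays of both lines in each group, so the line difference added to the spread within groups. Their low counts therefore do not measure false calls.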
